A study of Rattus norvegicus with 17 samples.

How the data were processed

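The samples are 17 regions of vessel endothelium from rats, each hybridized to 1 single-colour array. The labels give ligation surgery for the venous-flow vein and arteriovenous fistula surgery for the other groups. Per the labels, cells were laser-captured from sections of 10 µm, 10 captures were pooled, and 50 ng of RNA was amplified and labelled with cyanine dye. The deposited scanner output holds the mean signal, the mean local background and their difference for each spot as raw intensity, with no normalization, per the file headers. The scanner and its software are not given in the sources used here. The deposited value table holds log2 values, quantile normalized across arrays: the sorted columns differ by 2.43e-05 on average. It has values for 10000 of the 41372 gene probe spots (9879 different probes), and the criterion by which the depositors selected them is not given in the sources used here.

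The files were compared with each other before any test. On 11 of the 17 arrays the background column equals the mean of 2 other arrays within 0.001 intensity units, and outside the 10000 spots at least 92.7% of the signal does so as well. The planned filter by negative control spots, whose signal is filled in the same way, could therefore not be used, which departs from the plan. All 10000 spots were kept, and the planned filter that asks for detection in every array of a group was not run either. A test of only the features of highest mean, chosen later, stands among the alternatives. Signal exceeds the background column at every one of the 10000 spots, by at least 16.9 intensity units, but on 11 arrays that background is the filled one. The difference column of venous-flow vein 5 repeats that of vein 4, so signal minus background was computed instead. At most 7 probes on an array exceeded 65000 intensity units. On 12 arrays the scanner output matches the value table column of another sample. The scanner output with the sample of its own file was taken as the basis before any count of called features was seen, because the plan put scanner output first. Levels of a few vessel identity genes such as Gja5 had been looked at by then. The counts, set tests, named genes and overlap were also computed with the samples of the value table; the fits without 1 array, the other splits, the search for single arrays far from their group, the counts near the floor and the principal components were not.

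Signal was background-corrected with the normal-exponential model (offset 50), log2 transformed and quantile normalized over the 10000 spots with limma 3.58.1 in R 4.3.3. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9. Probes were matched to symbols by accession through a RefSeq table, which gives no coordinates, so genes are named by symbol alone. Of the spots, 3119 (31.2%) matched 1 symbol. The probe with the highest mean stood for each name, which left 9446 features: 2878 symbols and 6568 names without one. A feature without a symbol is given by the name on the array.

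One limma model was fitted to all 17 arrays with a mean per group, so that all groups share 1 estimate of the spread, and 6 contrasts were taken. P-values are 2-sided, from the moderated statistic of limma, with Benjamini-Hochberg adjustment within each contrast, and a feature was called at an adjusted p under 0.05. SD is over arrays and SE is that of the contrast. The labels do not tie regions to rats. Replicate numbers were checked as pairs: correlations of arrays with equal numbers, after group means were removed, ran from -0.607 to 0.328, and they were not used as pairs. A comparison of NIH vein with the other 12 arrays was added after seeing the data.

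The groups of genes and the rule for naming were written before the data were examined. Of 28 groups, 21 had at least 4 measured members and were tested with camera (preset correlation 0.01, adjusted over the groups of a contrast), again with an estimated correlation, and with fry, which tests whether the members move one way on balance. Members were also adjusted over the list alone. Named genes are, for each contrast, up to 8 with the largest rise and 8 with the largest fall among called genes for which every array of the first group lies on 1 side of the mean of the second. To these come up to 3 called members of each group, or up to 2 members with the smallest p, as values, where none was called.

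The method was tested on simulated data with the group sizes of the study, 9446 features and 100 changed features per fold size. It recovered between 50% and 69% of features changed by 1 on the log2 scale and between 78% and 93% of those changed by 2, and called 5 to 14 of 9246 unchanged features. Simulated features were independent of each other, which real ones are not. The simulated levels also had no floor, while the real ones have a floor of 5.64 and a median of 6.12. Simulated falls could therefore be larger than most real features can show. These shares may overstate what the method recovers in the real data. The overlap of both lesion sites was set beside 100 simulations of unchanged groups with shared controls and beside fits with the controls split. Other splits of the samples were counted for each contrast, at most 100.

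Alternatives fixed beforehand were subtracted background with quantile normalization, median scaling, the value table as deposited, the mean over the probes of a gene, a fit of only the groups compared, a block for the replicate number, array weights, a prior spread that varies with level, a fold change limit, and leaving out each array. Those chosen after seeing the data were both mixed pairings of values and samples, tests of only the genes with a symbol or only the 4723 features of highest mean, leaving out femoral artery 1 and venous-flow vein 3, and a covariate for the spread of signal within an array. A term for slide or scan batch was not fitted, since the file contents give neither.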

Results

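Gene expression was measured in endothelial cells taken from the inner surface of vessels in a rat study of the arteriovenous fistula operation. In this operation the superficial epigastric vein is joined to the common femoral artery, a model of the vascular access used for dialysis. Laser capture took the luminal cells 13 to 14 days after surgery, and each of the 17 regions was hybridized to 1 array. The NIH vein (n = 5) is vein under arterial flow with neointimal hyperplasia, a thickening of the inner wall. The stenotic side branch (n = 3) is a narrowed side branch of the same vein. The venous-flow vein (n = 6) lies beyond a ligation, saw no arterial flow and had no lesion, and the femoral artery (n = 3) was lesion free as well. The labels name ligation surgery for the venous-flow vein and fistula surgery for the other groups. In every comparison with the venous-flow vein, the surgery named cannot be told apart from the vessel. The regions are said to come from 6 rats, by which some arrays share a rat. Each sample title carries a different number, however, and whether these number animals is not given. No term for the animal could therefore be fitted, and the effect of shared rats on the p-values is unknown. The median signal above background ran from 28.5 to 80.9 intensity units across the arrays, and the number of arrays limits the precision of every value. An offset of 50 in the background correction puts a floor of 5.64 under the log2 levels, whose median was 6.12. Differences from a group whose mean lies within about 0.5 of that floor, a distance chosen after seeing the data, depend on the offset, no detection test could be made for them, and they are given on the log2 scale without a fold.

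Both forms of the deposited data, the scanner output of each array and the normalized value table, disagree on which sample is which. For the 5 NIH vein arrays the 2 forms gave the same ranks over 10000 probe spots. For the other 12 arrays the scanner output matched the value table column of another sample, with a rank correlation of 1.0000. The scanner output of stenotic side branches 1 to 3 matched the columns of venous-flow veins 1 to 3, and that of femoral arteries 1 to 3 matched the columns of venous-flow veins 4 to 6. Venous-flow veins 1, 5 and 6 matched the columns of stenotic side branches 1 to 3, and venous-flow veins 2 to 4 matched those of femoral arteries 1 to 3. Which assignment is right cannot be told from the sources used here. The values given first follow the scanner output, and for each comparison the counts and the values of the main genes and groups in the value table are given after them. A further fault limits the probes: on 11 of the 17 arrays the background column equals the mean of 2 other arrays within 0.001 intensity units, and the signal outside the 10000 spots is filled in the same way for at least 92.7% of probes. Only the 10000 spots, which the depositors selected, were therefore used. The 6 arrays with a background of their own are the 5 NIH veins and stenotic side branch 1. Every venous-flow vein and femoral artery has a filled background. In comparisons with the NIH vein, an effect of the filling cannot be told apart from the vessel type.

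**Figure D1:**
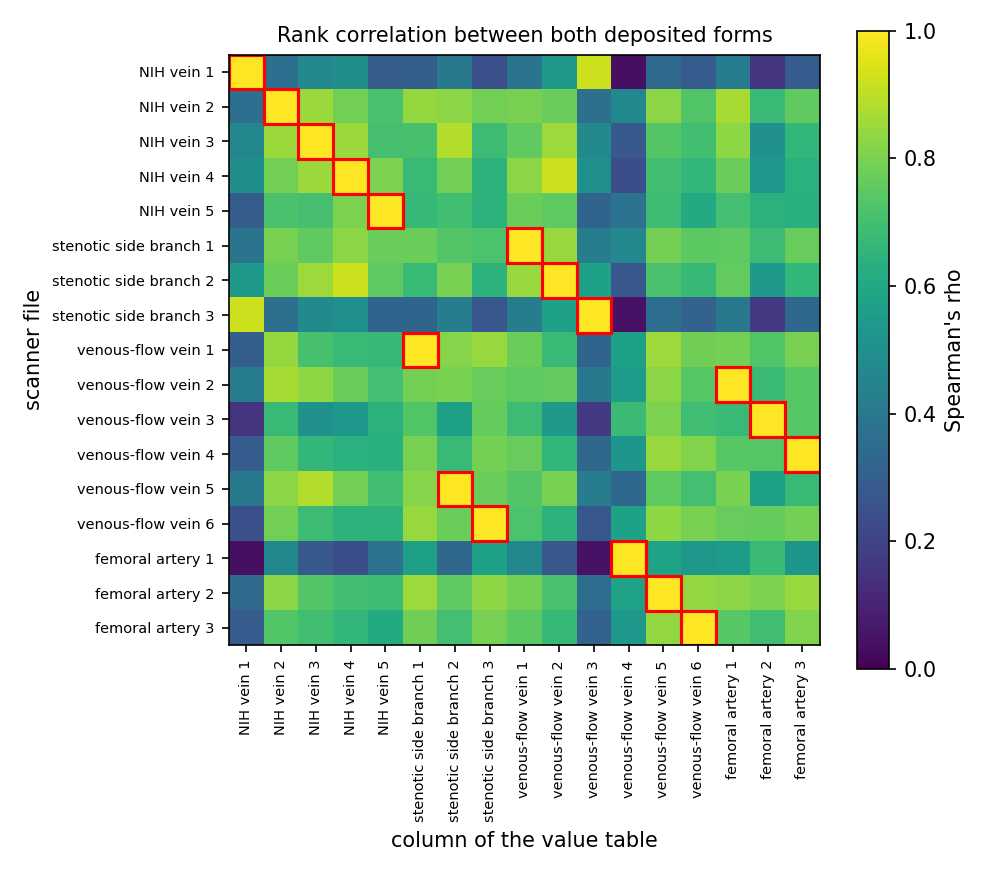
Spearman rank correlation between the scanner output of each array (vertical axis) and each value table column (horizontal axis) over 10000 probe spots, on a colour scale from 0 to 1. Red frames mark the matching column, which lies on the diagonal for the 5 NIH vein arrays and off it for the other 12 arrays.

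The comparison of NIH vein with venous-flow vein asks what differs in vein endothelium where the wall has thickened. Genes of the extracellular matrix were higher as a group in the NIH vein: 11 of the 12 measured members had a higher mean, and the median difference was 0.91 on the log2 scale. Col1a2, a chain of type I collagen, stood at 14.28 ± 0.89 (SD, n = 5) against 12.20 ± 1.12 (n = 6), a log2 difference of 2.07 ± 0.61 (SE) with an adjusted p of 0.16. Ccn2, a matrix-associated growth factor, stood at 8.90 ± 0.58 against 6.97 ± 0.87, a log2 difference of 1.92 ± 0.43 with an adjusted p of 0.0922. No single member of the list passed over all features tested, and 4 passed when adjusted over the list alone. The group was called by its set test (adjusted p = 0.00638) but not with an estimated correlation between genes (adjusted p = 0.792 with an estimated correlation). With the samples of the value table its median was 0.76 (adjusted p = 0.033), Col1a2 had a log2 difference of 2.11 (adjusted p = 0.74) and Ccn2 one of 1.97 (adjusted p = 0.285).

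Other genes of the NIH vein are given as values, since none with a symbol passed against venous-flow vein. Adm, the vasodilator peptide adrenomedullin, had a log2 difference of 2.10 ± 0.54 (adjusted p = 0.119), and Apoe, an apolipoprotein, one of 1.45 ± 0.34 (adjusted p = 0.0974). Snai1, a transcription factor of mesenchymal transition, had a log2 difference of -1.18 ± 0.28 (adjusted p = 0.104). Its other probe, not given for this comparison, had the opposite sign to this one in both comparisons of a lesion site with the femoral artery. Ndufv1, a subunit of respiratory complex I, had one of -1.37 (adjusted p = 0.0922). Snai1 and Ndufv1 shared 1 profile over the arrays, described below with the femoral artery, and are not separate findings. Esm1 and Vegfc, of the angiogenesis and tip cell group, had log2 differences of 0.97 and 0.73. The adhesion gene Selp had one of 0.72, and the junction genes Jam2 and Gja1 ones of -0.82 and -0.98. Adjusted p of these genes ran from 0.198 to 0.283. Their groups were not called: 3 of 8 angiogenesis and tip cell genes were higher (median -0.01), 4 of 8 adhesion genes (median -0.15) and 1 of 5 junction genes (median -0.64). The smooth muscle markers, which would come with cells from below the endothelium, had a median log2 difference of 0.13 over 8 measured members. Of the 9446 features tested, 3 passed, 2 higher and 1 lower, and 1550 had an unadjusted p under 0.05. All 3 lack a symbol and fall outside the rule for naming, so they were chosen after their values were seen: AI713966 rose by 2.91 and XM_341700 by 2.28 on the log2 scale, and TC538999 fell by 0.83, each with an adjusted p of 0.0373. Taking the value table's samples, 0 features passed in limma, 599 had an unadjusted p under 0.05, and these 3 kept their sign; Adm had a log2 difference of 2.87, Apoe one of 1.35, Snai1 one of -0.84 and Ndufv1 one of -1.01 there, with adjusted p of 0.303 for Adm and 0.74 for the others. The count was 0 without NIH vein 3 or 4 or without venous-flow vein 1, 3, 4 or 6, and it was 7, 81 and 25 without NIH vein 1, 2 and 5 and 27 and 274 without venous-flow vein 2 and 5. It was 15 with median scaling and 0 when only these 2 groups were fitted.

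The comparison of stenotic side branch with venous-flow vein asks the same of a narrowed vessel. Several genes of leukocytes rose in the stenotic side branch. Tyrobp, an adaptor protein of myeloid and natural killer cell receptors, stood at 9.35 ± 1.02 (SD, n = 3) against 7.13 ± 0.36 (n = 6), 4.67-fold higher (log2 2.22 ± 0.33 SE, adjusted p = 0.00719). C5ar1, the receptor of complement C5a, rose by 1.98 ± 0.35 (adjusted p = 0.0255), and Coro1a, an actin-binding protein of leukocytes, by 1.34 ± 0.21 (adjusted p = 0.00882). The kinase Lyn rose by 1.10 ± 0.15 and the lectin-like receptor Klra5 by 1.61 ± 0.22 (adjusted p = 0.00435 for both), and Igsf6 rose by 1.23 ± 0.17 (adjusted p = 0.00477). Hopx, a homeodomain protein, rose by 1.97 ± 0.36 (adjusted p = 0.0275) and Csk, a regulator of kinases such as Lyn, by 1.21 ± 0.23 (adjusted p = 0.0366). All 3 stenotic arrays lay above the venous-flow mean for each of these 8 genes.

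**Figure D2:**
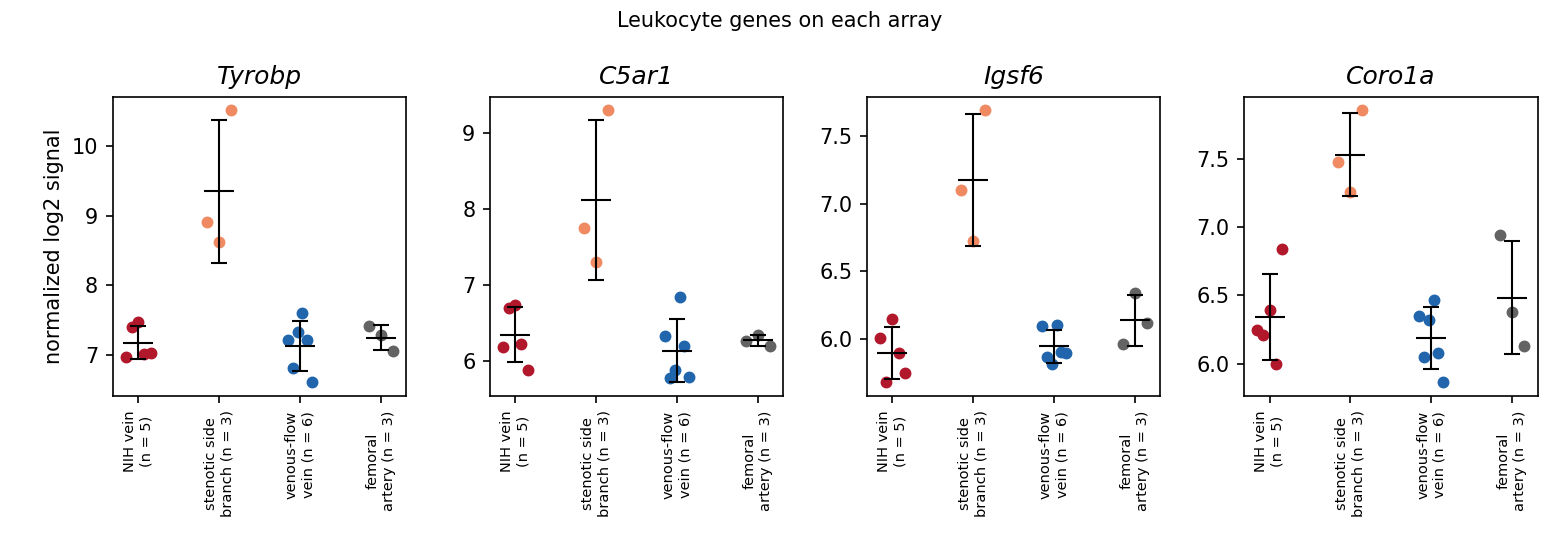
Normalized log2 signal (vertical axis) of 4 leukocyte genes on each of the 17 arrays, grouped as the scanner output assigns them; points are arrays and bars give the mean and SD of each group. The 3 stenotic side branch arrays lie above all other arrays for Tyrobp, C5ar1, Igsf6 and Coro1a; in the value table these 3 arrays are venous-flow veins 1 to 3.

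Of the 10 measured macrophage and myeloid markers, 9 were higher in the stenotic side branch (median log2 difference 0.67); 2 passed over all features and 6 when adjusted over the list alone. The set test called the group (adjusted p = 5.51e-06; adjusted p = 0.0908 with an estimated correlation). Of 8 measured genes of interferon response and antigen presentation, 7 were higher (median 0.87); none passed over all features and 6 passed when adjusted over the list alone (set test adjusted p = 0.000184; adjusted p = 0.159 with an estimated correlation). Among them, Irf7, a regulator of interferon genes, had a log2 difference of 1.07 (adjusted p = 0.0548) and Cd74, the invariant chain of antigen presentation, one of 0.44 (adjusted p = 0.0521). Matrix genes were higher in 11 of 12 members (median 0.51; 1 passed when adjusted over the list alone; set test adjusted p = 0.0241; adjusted p = 0.531 with an estimated correlation). Their members Timp1, an inhibitor of matrix proteases, and Col1a2 had log2 differences of 1.65 (adjusted p = 0.0548) and 2.19 (adjusted p = 0.159). The matrix call was lost without stenotic side branch 1, venous-flow vein 5 or venous-flow vein 6. The endothelial junction genes had a median of -0.75 over 5 members without passing (adjusted p = 0.0704).

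In all, 35 features were higher and 2 lower in the stenotic side branch than in the venous-flow vein, 14 of them with a symbol, and 1612 had an unadjusted p under 0.05. Under the other assignment, 20 features were higher and 0 lower, none of them among the 37, and all 37 had the opposite sign. There Tyrobp had a log2 difference of -1.44 and C5ar1 one of -1.36, and the myeloid and matrix groups were called lower (medians -0.69 and -0.56, adjusted p = 0.000104 and 0.00642). The interferon group had a median of -0.18 (adjusted p = 0.674), and Irf7, Cd74, Timp1 and Col1a2 had log2 differences of -0.42, -0.45, -1.01 and -0.27. In 20 of the 37 features, C5ar1, Hopx, Klra5, Igsf6 and Lyn among them, the lower mean lies within 0.5 of the floor. The count was 8 without stenotic side branch 3, which ends the calls of C5ar1, Coro1a and Csk, and 114 without stenotic side branch 1. It was 18, 18, 22, 128 and 17 without venous-flow vein 1, 2, 3, 5 and 6; C5ar1, Hopx and Csk lost their call without vein 1, 2, 3 or 6, and Csk also without stenotic side branch 2. Subtraction of background in place of its model gave 65 higher and 26 lower, and median scaling gave 5 higher and 0 lower.

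The direct comparison of both lesion sites asks how a narrowed side branch differs from a thickened vein. Both genes with a symbol that passed, Tyrobp and Igsf6, rose in the stenotic side branch. Tyrobp was 4.52-fold higher, at 9.35 ± 1.02 (SD, n = 3) against 7.17 ± 0.24 (n = 5), with a log2 difference of 2.18 ± 0.34 (SE, adjusted p = 0.0389). Igsf6 rose by 1.28 ± 0.17 on the log2 scale, from 5.90 ± 0.19, near the floor, to 7.17 ± 0.49 (adjusted p = 0.0132). The myeloid group was higher in 9 of 10 members (median 0.80; 1 passed over all features and 6 when adjusted over the list alone; set test adjusted p = 2.46e-14; adjusted p = 0.00269 with an estimated correlation). The interferon group was higher in 7 of 8 (median 0.64; none passed over all features and 5 when adjusted over the list alone; set test adjusted p = 1.72e-10; adjusted p = 0.0077 with an estimated correlation). Oas1a, an interferon-induced antiviral enzyme, stood at 8.22 ± 0.38 against 6.77 ± 0.52 (log2 1.45, adjusted p = 0.192).

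Ccn2 had a log2 difference of -1.63 between stenotic side branch and NIH vein (adjusted p = 0.732), and Adm one of -1.84 (adjusted p = 0.952). In all, 6 features were higher and 0 lower, 2 of them with a symbol, and 336 had an unadjusted p under 0.05. Under the other assignment, 23 were higher and 4 lower, none shared with the 6, of which 1 kept its sign. There Tyrobp had a log2 difference of -0.20, Igsf6 one of 0.12, Oas1a one of 0.58 and Adm one of -1.76, Ccn2 passed with -2.90 (adjusted p = 0.038), and the myeloid and interferon groups were not called (medians -0.19 and 0.22, adjusted p = 0.49 and 0.273). The count was 2 without stenotic side branch 1, 10 without stenotic side branch 2, and 3, 1, 2 and 2 without NIH vein 1, 2, 3 and 4; Tyrobp lost its call without stenotic side branch 1 or any single NIH vein, and Igsf6 without stenotic side branch 1 or NIH vein 2. It was 3 with background subtracted, 2 with median scaling and 0 when only these 2 groups were fitted.

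The comparison of femoral artery with venous-flow vein sets both lesion-free vessels side by side. Genes of lipid uptake and transport were lower in the artery in 5 of 5 measured members, with a median log2 difference of -0.83 (set test adjusted p = 0.00359; adjusted p = 0.0684 with an estimated correlation). None of them passed alone or when adjusted over the list alone. The transcription factor Meox2 had a log2 difference of -1.60 and the lipoprotein receptor Scarb1 one of -1.06 (adjusted p = 0.858 for both). Gja5, a connexin of arterial endothelium, stood at 8.79 ± 0.71 (SD, n = 3) in the artery against 7.80 ± 0.85 (n = 6) in the vein, a log2 difference of 0.98 ± 0.43 (SE, adjusted p = 0.858). The vein is also the vessel with the higher Col1a2 mean, at 12.20 ± 1.12 against 9.99 ± 1.25 (log2 -2.21, adjusted p = 0.858). The red cell and platelet markers had a median of 0.51 (set test adjusted p = 0.0514). No feature passed in limma, 464 had an unadjusted p under 0.05 and the smallest adjusted p was 0.448. The value table's samples gave 0 as well, with 149 at an unadjusted p under 0.05, and there the lipid group had a median of -0.22 (adjusted p = 0.903), Gja5 had a log2 difference of 0.68, Meox2 one of -0.13 and Scarb1 one of -0.38, and the difference of Col1a2 had the opposite sign, at 0.32 (adjusted p = 0.999 for each gene). The lipid call was lost without femoral artery 1.

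The comparison of NIH vein with femoral artery sets vein with a lesion against artery without one, both under arterial flow. Col1a2, Ctsl and Adm were among the genes that rose most in the NIH vein. Col1a2 was 19.5-fold higher, at 14.28 ± 0.89 (SD, n = 5) against 9.99 ± 1.25 (n = 3), with a log2 difference of 4.28 ± 0.74 (SE, adjusted p = 0.016); a weaker probe of it, with a mean level of 6.20, gave 0.36 (adjusted p = 0.387 over probes). Ctsl, the lysosomal protease cathepsin L, was 12.9-fold higher (10.60 ± 0.57 against 6.91 ± 0.65, adjusted p = 0.0155). Igfbp3, a binding protein of insulin-like growth factors, was 7.58-fold higher (log2 2.92, adjusted p = 0.0302); its weaker probe gave a log2 difference of 1.11 (adjusted p = 0.0214 over probes). Adm rose by 3.22 ± 0.66 on the log2 scale (adjusted p = 0.0239) and Apoe by 2.28 ± 0.41 (adjusted p = 0.0199), with femoral artery means of 6.15 ± 0.41 and 5.90 ± 0.08, close to the floor. Il1rl1, the interleukin 33 receptor, rose by 3.84 on the log2 scale, the cadherin Fat1 by 3.12, the presenilin Psen2 by 2.61 and the ribosomal protein gene Rps2 by 2.51, whose other 3 probes gave 0.39, 1.35 and 1.79.

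Among genes that were lower in the NIH vein than in the femoral artery, the connexin Gjd3 fell by 2.43 ± 0.48 (log2, SE, adjusted p = 0.0217) and Gdnf, a neurotrophic factor, fell by 2.14 ± 0.43 (adjusted p = 0.0233). Fkbpl fell by 2.21, the adaptor Grb7 fell by 2.01, the neuropeptide gene Adcyap1 fell by 1.98 and Cog7, of the Golgi, fell by 1.76. Ndufv1 fell by 1.91 (adjusted p = 0.0216), and Ptgis, the prostacyclin synthase, fell by 0.78 (adjusted p = 0.0493). Snai1 fell by 1.69 and Exoc6 fell by 1.95, but the other probe of each had the opposite sign, without passing. All of these lower genes but Ptgis shared 1 profile over the arrays. In each, venous-flow vein 3 was highest and vein 5 lowest in their group, and NIH vein 2 was highest in its group. Femoral artery 1 was highest in its group as well. Venous-flow vein 3 and femoral artery 1 had the lowest spread of signal (log2 of the upper quartile over the median, 0.312 and 0.233). Vein 5 had the highest of the venous-flow veins (1.00). The NIH veins did not follow this order, with 0.903 in vein 2 and 0.818 in vein 5. The genes of this profile may therefore stand for 1 pattern across arrays and are not separate findings. An effect of the spread of signal on them cannot be told apart from the vessel type. Of the 87 genes with a symbol that passed, 14 have at least 2 probes, and for 11 of these the probes differ in sign. Gja5 had a log2 difference of -1.39 (adjusted p = 0.0834). The matrix group was higher in 11 of 12 members (median 1.31; 1 passed over all features and 6 when adjusted over the list alone; set test adjusted p = 0.0119; adjusted p = 0.672 with an estimated correlation). The ribosomal protein genes were higher in 17 of 21 members and the lipid genes in 5 of 5, without the set test passing (adjusted p = 0.0689 for both).

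**Figure D3:**
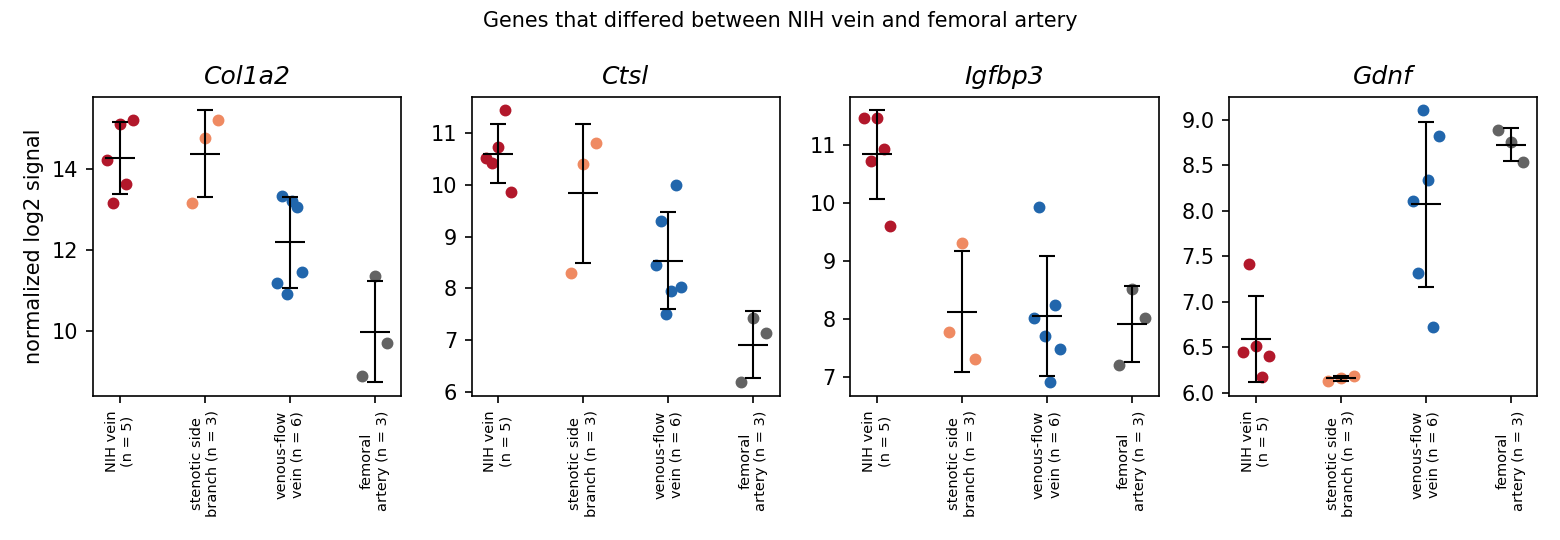
Normalized log2 signal (vertical axis) of Col1a2, Ctsl, Igfbp3 and Gdnf on each of the 17 arrays, grouped as the scanner output assigns them; points are arrays and bars give the mean and SD of each group. Every NIH vein array lies above the 3 femoral artery arrays for the first 3 genes and below them for Gdnf.

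In all, 160 features were higher and 76 lower in the NIH vein than in the femoral artery, and 2374 had an unadjusted p under 0.05. Under the other assignment, 0 features passed in limma and 1036 had an unadjusted p under 0.05; 235 of the 236 had the same sign there. In the value table Col1a2 had a log2 difference of 1.79 (adjusted p = 0.61), Ctsl one of 2.48, Adm one of 2.94, Igfbp3 one of 2.82, Gdnf one of -1.96 and Snai1 one of -1.53 (adjusted p = 0.441 for each of these 5), Apoe one of 1.57 (adjusted p = 0.487) and Gja5 one of -1.02 (adjusted p = 0.607). The matrix group was not called there (median 0.49, adjusted p = 0.35). In 79 of the 236 features the lower mean lies within 0.5 of the floor. The count was 0 without femoral artery 1 or 3, so that each call above, Col1a2 to Exoc6, was lost, and 128, 543, 99, 22 and 416 without NIH vein 1, 2, 3, 4 and 5; the matrix group also lost its call without femoral artery 1, and without both femoral artery 1 and venous-flow vein 3 (adjusted p = 0.178). Median scaling gave 46 higher and 3 lower, and a prior spread that varies with level gave 139.

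The comparison of stenotic side branch with femoral artery is the other contrast of lesion and artery. Col1a2, Ctsl and Tyrobp were among the genes that rose in the stenotic side branch. Col1a2 was 21-fold higher, at 14.39 ± 1.07 (SD, n = 3) against 9.99 ± 1.25 (n = 3), with a log2 difference of 4.39 ± 0.83 (SE, adjusted p = 0.024); its weaker probe gave 0.58 (adjusted p = 0.24 over probes). Ifi30, a lysosomal enzyme of antigen processing, rose by 2.49 ± 0.47, Apoe by 2.42 ± 0.46 and Tyrobp by 2.11 ± 0.38 (adjusted p = 0.024 for each). Ctsl rose by 2.92 (adjusted p = 0.045), Pcolce, an enhancer of procollagen processing, by 2.50 (adjusted p = 0.0369), the lysosomal fucosidase Fuca1 by 2.20 (adjusted p = 0.0246; its weaker probe gave 0.42, adjusted p = 0.313 over probes) and the lactate transporter Slc16a3 by 2.17 (adjusted p = 0.0435). Kdr, a receptor of vascular endothelial growth factor, rose by 1.95 ± 0.46 (adjusted p = 0.0468), Sh3glb1 by 2.40 and Coro1a by 1.05.

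Among genes that were lower in the stenotic side branch than in the femoral artery, Gja5 fell by 2.08 ± 0.50 (log2, SE, adjusted p = 0.0474), Gjd3 fell by 2.76 (adjusted p = 0.0246), Gdnf fell by 2.57 (adjusted p = 0.024) and Ndufv1 fell by 2.18 (adjusted p = 0.0246). Adcyap1 fell by 2.40, Grb7 fell by 2.31 and Fkbpl fell by 2.32. Snai1 fell by 1.88 and Exoc6 fell by 2.30, again with the other probe of opposite sign. All of these lower genes but Gja5 are among those that shared 1 profile over the arrays. The set test called 4 groups higher. These were matrix genes (11 of 12 members, median 1.05, 1 passed over all features and 4 when adjusted over the list alone, adjusted p = 0.00863), myeloid markers (8 of 10, median 0.73, 2 and 5, adjusted p = 0.00453), interferon genes (7 of 8, median 0.98, 0 and 6, adjusted p = 0.00284) and lipid genes (4 of 5, median 1.09, 1 and 2, adjusted p = 0.0333). None was called with an estimated correlation (adjusted p = 0.489 for matrix genes and 0.183 for the others, with an estimated correlation). The junction genes were lower in 5 of 5 members (median -0.93, adjusted p = 0.0571).

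In all, 110 features were higher and 65 lower in the stenotic side branch than in the femoral artery, 65 of the 175 with a symbol, and 2183 had an unadjusted p under 0.05. Taking the value table's samples, 17 were higher and 2 lower, none of them among the 175, of which 114 kept their sign. There Col1a2 had a log2 difference of -0.59, Tyrobp one of -0.28, Ctsl one of 0.63, Kdr one of 0.72, Gdnf one of -0.43 and Gja5 one of -1.16 (adjusted p = 1 for each), matrix genes were called lower (median -0.68, adjusted p = 0.000391), interferon and lipid genes were called higher (medians 0.57 and 0.54, adjusted p = 0.00649 for both), and myeloid markers were not called (median -0.26, adjusted p = 0.0935). In 91 of the 175 features the lower mean lies within 0.5 of the floor. The count was 518, 24 and 1 without stenotic side branch 1, 2 and 3 and 7, 45 and 1 without femoral artery 1, 2 and 3, and each of the named calls was lost in at least 3 of these 6 fits. Matrix and lipid genes lost their call without femoral artery 1, and lipid genes also without stenotic side branch 1 or 2. Median scaling gave 1 feature, and a fit of only these 2 groups gave 15 higher and 45 lower.

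Of the 126 set tests over 6 comparisons, 12 were called, and 2 of them with an estimated correlation, the myeloid and interferon groups between stenotic side branch and NIH vein. The matrix, myeloid, interferon and lipid groups account for all 12. With the samples of the scanner output, the other 17 tested groups were called in none of the 6 comparisons, among them arterial and venous identity, flow response, adhesion, coagulation, proliferation, hypoxia and smooth muscle. Under the other assignment, 24 set tests were called with the preset correlation, not only in these 4 groups. There the stenotic side branch was called higher than venous-flow vein and femoral artery for flow response (adjusted p = 0.00642 and 0.00399), adhesion (0.0417 and 0.0158), coagulation (0.0359 and 0.0115), immediate early genes (0.00727 and 0.000391) and mitochondrial respiration (0.00642 and 0.0302), and lower for red cell and platelet markers (0.00727 and 0.024). Matrix genes were called lower in the stenotic side branch than in the NIH vein (median -1.51, adjusted p = 9.48e-06), and lipid genes higher in it than in venous-flow vein (adjusted p = 0.00642). Against venous-flow vein, myeloid markers were called lower in the NIH vein (adjusted p = 0.00121) and the femoral artery (adjusted p = 0.00427), interferon genes lower in the femoral artery (adjusted p = 5.28e-05) and ribosomal protein genes higher in the NIH vein (adjusted p = 0.033).

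Both lesion sites shared 2 features that passed in the same direction against the venous-flow vein, 1 higher and 1 lower: XM_341700 and TC538999. Independent lists of these sizes would share 0.00741 higher and 0.000212 lower features. In 100 simulations of unchanged groups that share the 6 control arrays the overlap was 0. With different control arrays for the 2 comparisons it was 0 or 1 over the 20 ways of splitting them. Across features, which are not independent replicates, the log2 differences of both comparisons had a covariance of 0.243, against 0.042 for simulated unchanged groups and 0.208 with split controls. Real features move together: other splits of the arrays called up to 498 and 358 features. Single lesion arrays also resemble each other, with a rank correlation of 0.923 between NIH vein 1 and stenotic side branch 3. Splitting the controls does not remove this, so chance is not excluded for the overlap. With the samples of the value table the overlap was 0. The overlap was also 0 without NIH vein 3 or 4, stenotic side branch 3 or venous-flow vein 1, 3, 4 or 6. It was 1 without stenotic side branch 2, 25 without NIH vein 2 and 69 without venous-flow vein 5, and 0 with median scaling.

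Because both forms of the data give the same 5 arrays to the NIH vein, a comparison of these with the other 12 arrays, chosen after seeing the data, does not depend on the disagreement. It mixes 3 vessel types in its second group. Of those 12 arrays, 11 have a filled background, while all 5 NIH vein arrays have their own. An effect of this cannot be told apart from the vessel type. Igfbp3 was 6.97-fold higher in the NIH vein, at 10.84 ± 0.76 (SD, n = 5) against 8.03 ± 0.87 (n = 12), with a log2 difference of 2.80 ± 0.43 (SE, adjusted p = 0.0291); its weaker probe gave 1.44 (adjusted p = 0.00408 over probes). Ubd, a ubiquitin-like protein induced by cytokines, rose by 2.00 ± 0.36 (adjusted p = 0.0488), the G protein subunit Gna14 by 1.11 ± 0.19 (adjusted p = 0.0461), the growth factor Nrg1 by 0.79 ± 0.13 (adjusted p = 0.0316) and Serpinb6b by 0.34 ± 0.06 (adjusted p = 0.0488). All 5 NIH vein arrays lay above the mean of the others for each of these 5 genes. The other probe of Nrg1 had the opposite sign, at -0.36 (adjusted p = 0.555 over probes), and the mean of Nrg1 in the other arrays, 5.90 ± 0.23, is near the floor. The means of Gna14 and Serpinb6b in the other arrays are near the floor as well. Serpinb6b reached at most 6.27 on an NIH vein array. The values of the value table gave Igfbp3 2.96 (adjusted p = 0.0325), Ubd 2.45, Gna14 1.53, Nrg1 1.13 and Serpinb6b 0.52, of which Serpinb6b did not pass (adjusted p = 0.0672). The matrix group was higher in 11 of 12 members (median 0.69; 0 passed over all features and 1 when adjusted over the list alone; set test adjusted p = 0.0167; adjusted p = 0.688 with an estimated correlation).

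In this comparison of NIH vein with all other arrays 9 features were higher and 0 lower, and 1196 had an unadjusted p under 0.05. The value table gave 7 higher and 0 lower, all 7 among the 9. The count was 0 without venous-flow vein 1, 3 or 5 or femoral artery 1 or 3. It was 2 without NIH vein 4, venous-flow vein 4 or femoral artery 2, 3 without stenotic side branch 1, 15 without venous-flow vein 2, and 16 without NIH vein 5 or stenotic side branch 3. Igfbp3 lost its call in 7 of the 17 fits that leave out 1 array, those without NIH vein 1 or 4, venous-flow vein 1, 3 or 5 or femoral artery 1 or 3, and Ubd, Gna14, Nrg1 and Serpinb6b in 13, 12, 9 and 14 of them. Median scaling gave 29 features, and the mean over the probes of a gene gave 2.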

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

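The test of the myeloid members as a set, that of the smooth muscle members and those of the other sample assignment were chosen after the results were seen. The comparison of NIH vein with the other 12 arrays, the fit without 2 arrays and the covariate for the spread of signal were added after seeing the data. The rest were chosen before. Each of the 80 combinations of a named gene and a group of 5 or 6 arrays was searched for 1 array far from the others, by its gap to the nearest array as a share of the range of the group. This found 8, where chance gives about 4. In the NIH vein, Adm was low in array 5 (share 0.714; log2 level 7.32, nearest 9.43) and Gdnf was high in array 2 (share 0.725; 7.41, nearest 6.52). In the venous-flow vein, 4 of the 6 were in array 2, which was high for Il1rl1 (share 0.811; 9.77, nearest 6.50), Gna14 (share 0.802; 6.75, nearest 5.88), Nrg1 (share 0.727; 6.46, nearest 5.90) and Serpinb6b (share 0.704; log2 level 6.10). Ptgis was high in venous-flow vein 3 (share 0.747; 6.59, nearest 5.95) and Pcolce in venous-flow vein 4 (share 0.643; log2 level 7.82).

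The first pattern weighed is the rise of myeloid genes such as Tyrobp in the stenotic side branch. Leukocyte RNA among the captured cells is a candidate source. Of the 10 measured markers, 9 had a higher mean there than in the NIH vein, with a median log2 difference of 0.80. C1qb and Laptm5, chosen after their values were seen, stood at 9.98 ± 1.39 and 9.73 ± 0.65 (SD, n = 3) against 7.30 ± 0.64 and 8.56 ± 0.73 (n = 5). These values are the pattern itself, so they cannot tell leukocyte RNA from a change in the endothelial cells. Cd74 belongs to the interferon group as well, and laser capture takes cells by place, so it does not remove leukocytes on the vessel wall. A wrong sample assignment is the technical explanation, and what it needs is there: with the samples of the value table the median was -0.19, since these 3 arrays are then venous-flow veins. Both stay open because no source used here says which assignment is right, and a change in the endothelial cells themselves was not tested.

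The second pattern is the set of 236 features called between NIH vein and femoral artery, with a median absolute log2 difference of 1.52 and a median SE of 0.32. Without femoral artery 1 and venous-flow vein 3, the arrays with the lowest spread of signal, the median feature had a share of 0.912 of its log2 difference (quartiles 0.84 and 0.961). Venous-flow vein 3 does not enter this difference of group means, and the arrays were not normalized again. The share therefore argues only against femoral artery 1 as the whole source of the size. It does not decide on weak signal in the other arteries. The count still fell from 236 to 2, with a median difference of 1.31 and a median SE of 0.34. It was also 0 without femoral artery 1 or 3 alone, but 243 without femoral artery 2. The loss of 1 artery therefore did not by itself end the calls, which depended on the artery left out. Why they did was not tested. With a covariate for the spread of signal within an array the share was 0.645 and the count 0 (median difference 0.94, median SE 0.33), and with the samples of the value table the share was 0.689 and the count 0 (1.01 and 0.45). Both may account for a part of the differences, and neither can be told apart from the vessel types, which differ in the spread of signal and whose assignment is unknown.

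The third pattern is the higher level of matrix genes in the NIH vein than in the venous-flow vein. With the samples of the value table their median log2 difference was 0.76, against 0.91, and the set test passed there too (adjusted p = 0.033), which argues against a wrong assignment as its whole source. The call itself rests on the preset correlation: it has an adjusted p of 0.792 with an estimated correlation and of 0.0784 by fry. Cells from below the endothelium may add matrix RNA: the 8 measured smooth muscle markers had a median of 0.13, but with an SD of 0.34 over the members this does not decide. Fibroblasts had only 3 measured markers, 1 higher and 2 lower (median -0.04), too few to decide. A change in the endothelial cells of the thickened vein stays open as an untested explanation.

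Other splits of the samples into groups of equal sizes were fitted in the same way. These counts take the regions as exchangeable, which regions from a shared rat are not. The 7 shares were also not adjusted for their number. A share under 0.05 therefore does not exclude chance, even for independent regions. For NIH vein against venous-flow vein, 4 of 100 splits called at least 3 features, a share under 0.05, but the highest other split called 498. That split set NIH vein 2 and venous-flow veins 1, 3, 4 and 6 against the rest, which points to a structure among the samples that the groups do not follow. For stenotic side branch against venous-flow vein, 4 of 84 splits called at least 37, and the highest other, venous-flow veins 3, 4 and 6 against the rest, called 358, about which the same holds: the share is under 0.05, and the samples have a structure of their own that chance groupings can follow. For stenotic side branch against NIH vein, 6 of 56 splits called at least 6 (highest other 418), and chance is not excluded. For femoral artery against venous-flow vein all 84 splits called at least 0 (highest other 141). For NIH vein against femoral artery, 2 of 56 splits called at least 236, a share under 0.05, but the highest other called 296, more than the real one. For stenotic side branch against femoral artery there are only 10 splits, too few for a share under 0.05; the real one called 175 and the highest other 0, so 1 of 10 was as large. For NIH vein against the other 12 arrays, 3 of 100 splits called at least 9, a share under 0.05 (highest other 17).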

How the results depend on the processing

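The alternatives that change which sample an array belongs to, the tests of only part of the features, the fit without 2 arrays, the covariate and everything on NIH vein against the other 12 arrays were chosen after seeing the data; the rest were chosen before. Counts of features follow in a fixed order: NIH vein against venous-flow vein, stenotic side branch against venous-flow vein, stenotic side branch against NIH vein, NIH vein against femoral artery, stenotic side branch against femoral artery, NIH vein against the other 12 arrays, and the overlap of both lesion sites. The reported counts are 3, 37, 6, 236, 175, 9 and 2. Femoral artery against venous-flow vein stayed at 0 under every alternative run. Where only the value that moved is given, the others were within 1.5 times of the reported count; the cause was not tested unless said.

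Subtracted background gave 91 for stenotic side branch against venous-flow vein and 3 for stenotic side branch against NIH vein, and so did the value table with the samples of the scanner output. Median scaling gave 15, 5, 2, 49, 1, 29 and 0. The value table as deposited gave 0, 20, 27, 0, 19, 7 and 0, and scanner values with the samples of the value table gave 0, 27, 30, 0, 26, 9 and 0. The mean over the probes of a gene gave 2 for NIH vein against the other arrays. Fitting only the groups compared gave 0, 86, 0, 258 and 60, with fewer arrays to estimate the spread. The block for replicate number gave 0, 1, 1, 0, 1, 0 and 0, although the numbers do not pair the arrays. Array weights gave 253, 3803, 423, 745, 2661, 196 and 217, but their estimation stopped before it converged, so these counts carry little weight. A prior spread that varies with level gave 1, 107, 8, 139, 156, 8 and 0. Testing only genes with a symbol gave 0, 36, 5, 113, 73, 5 and 0, with fewer features tested, and the 4723 features of highest mean gave 8, 72, 5, 646, 200, 4 and 3. Without the 2 arrays of weakest signal the counts were 1, 16, 2, 2, 1, 0 and 1, and with the covariate for the spread of signal 0, 31, 5, 0, 1, 0 and 0. A log2 difference of at least 1 left 2, 24, 5, 171, 136 and 4. Splitting the controls gave an overlap of 0 to 1.

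Leaving out 1 array at a time gave ranges of 0 to 274, 8 to 128, 1 to 10, 0 to 543, 1 to 518, 0 to 16 and, for the overlap, 0 to 69. The highest came without venous-flow vein 5, venous-flow vein 5, stenotic side branch 2, NIH vein 2, stenotic side branch 1, NIH vein 5 or stenotic side branch 3, and venous-flow vein 5. The number of called set tests, 12 as reported, was 2 with an estimated correlation, 11 by fry (8 of the 12 and 3 others), 24 with the value table as deposited, 25 with scanner values under its samples, and 10 to 17 when 1 array was left out. By fry the matrix calls were lost for NIH vein and stenotic side branch against venous-flow vein (adjusted p = 0.0784 and 0.118) and for stenotic side branch against femoral artery (0.0524), as was the lipid call of femoral artery against venous-flow vein (0.0619); lipid genes (0.0114) and junction genes (0.0353) of NIH vein against femoral artery and junction genes of stenotic side branch against femoral artery (0.00963) were added. The matrix call of NIH vein against femoral artery was lost with the value table as deposited (0.35) and with scanner values under its samples (0.358).

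Among 54 calls of named genes, 53 passed with subtracted background, 12 with median scaling, 7 without the 2 weakest arrays, 9 with the covariate and 0 with the replicate block, all with the same sign; of 445 fits of a named call without 1 array, 248 lost the call and none changed sign. The sample assignment alone reversed signs. In what follows the first value is from the value table as deposited and the second from scanner values with its samples. Stenotic side branch against venous-flow vein gave log2 differences of -1.44 and -1.29 for Tyrobp, -1.36 and -1.09 for C5ar1, -0.99 and -0.85 for Hopx, -1.34 and -1.01 for Klra5, -1.18 and -0.91 for Coro1a, -0.93 and -0.69 for Igsf6, -0.91 and -0.75 for Csk, and -0.65 and -0.49 for Lyn. Against NIH vein, Tyrobp gave -0.20 and -0.16. Against femoral artery, Col1a2 gave -0.59 and -0.58, Pcolce -0.47 and -0.39, Ifi30 -0.57 and -0.49, Apoe -0.22 and -0.17, Sh3glb1 -0.19 and -0.18, Slc16a3 -0.30 and -0.25, Tyrobp -0.28 and -0.24, and Coro1a -0.27 and -0.18. Set tests that turned to lower in the stenotic side branch had adjusted p of 0.00642 and 0.00641 (matrix), 0.000104 and 0.000187 (myeloid) and 0.674 and 0.586 (interferon) against venous-flow vein, 0.49 and 0.554 (myeloid) against NIH vein, and 0.000391 and 0.000602 (matrix) and 0.0935 and 0.116 (myeloid) against femoral artery. A filter on detection could not be run, because the negative controls are filled in on 11 arrays. Among the features of highest mean, 51 of the 51 named calls tested there and 11 of the 12 called groups still passed; the lipid genes of stenotic side branch against femoral artery did not (adjusted p = 0.0614). Median signal above background was 28.5 intensity units on femoral artery 1, against a median background column of 54.6 that is itself filled in.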

Other observations

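Genes of TGF-beta signalling and mesenchymal transition were not called as a group in any comparison, with either sample assignment. Between NIH vein and femoral artery 1 member passed, Snai1, whose other probe had the opposite sign. Tgfbr1, a receptor of this pathway, had a log2 difference of -3.29 without passing (adjusted p = 0.0753) and Twist1 one of -0.64 (adjusted p = 0.0574). Against venous-flow vein, Tgfbr1 had one of -2.37 (adjusted p = 0.184) and S100a4 one of 2.04 (adjusted p = 0.162). These values of Tgfbr1, Twist1 and S100a4 were chosen after they were seen. Twist1 and Snai1 both had the profile over the arrays that genes lower in the NIH vein than in the femoral artery shared, so they are not separate findings. The identity gene Gja5 stood at 8.79 ± 0.71 (SD) in the femoral artery (n = 3), 7.80 ± 0.85 in the venous-flow vein (n = 6), 7.39 ± 0.16 in the NIH vein (n = 5) and 6.70 ± 0.56 in the stenotic side branch (n = 3). Of the 20 pan-endothelial markers only Kdr was among the measured genes, so the purity of the captured endothelium could not be checked with that group.

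Some arrays resemble arrays of another group more than those of their own. Over the 10000 probe spots, which are not independent, the rank correlation was 0.923 between NIH vein 1 and stenotic side branch 3 and also 0.923 between NIH vein 4 and stenotic side branch 2, with samples as in the scanner output. NIH vein 1 had values of only 0.296 to 0.498 with the other NIH veins, and stenotic side branch 3 of 0.425 to 0.571 with the other stenotic side branches, so both stand apart within the groups whose means and SDs include them. Without NIH vein 1, 7, 3 and 128 features passed against venous-flow vein, stenotic side branch and femoral artery, in place of 3, 6 and 236. Without stenotic side branch 3, 8, 4 and 1 passed against venous-flow vein, NIH vein and femoral artery, in place of 37, 6 and 175. Femoral artery 1 had a rank correlation of 0.04 with NIH vein 1. The first principal component held 46.4% of the variance of normalized values, the second 15.3% and the third 12.9%. On the first, NIH vein 1 and stenotic side branch 3 lay at -63 and -59.3, and venous-flow vein 4, femoral artery 1 and femoral artery 3 at 43.1, 44.8 and 45.2. The titles of these arrays carry different numbers, but whether arrays that resemble each other come from 1 rat is not given in the labels.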
